A study of Drosophila melanogaster with 4 samples.

How the data were processed

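The series holds 4 samples of Drosophila melanogaster embryos of the wild-type strain Oregon-R at 14 to 16 h of development: 2 chromatin immunoprecipitation (ChIP) samples made with antibody Q2634 against JHDM1, and 2 input samples of chromatin DNA that was not immunoprecipitated. The embryos were crosslinked with 1.8% formaldehyde and the chromatin was incubated with antibody for 15 h, per the labels' protocols. Each ChIP replicate has a list of enriched regions, called clusters here, and 1 more list covers the replicates together. The input libraries were not analysed here. According to the labels, input replicate 1 served for the list of ChIP replicate 2 and input replicate 2 for that of ChIP replicate 1. The labels call the samples replicates without saying that they came from separate embryo collections, so the spread between them may be technical.

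Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The lists hold regions of significant enrichment on FlyBase release 5 of the genome, per the file headers. The program that called the regions, its threshold, the way the input entered the call, the way the replicates were combined and the read depth of each library are not given in the sources used here. Each region carries 1 score that the authors deposited without stating its scale. The score is the authors' own value for that region. It was used to describe and rank regions within a list and to correlate paired regions between lists. Scores of paired regions were also averaged over the replicates, and their differences were described. A difference in score level between lists is not a difference in binding, since each list has its own score. With no read counts in the lists, the depth behind a cluster is unknown.

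The coordinates are those of the deposited lists, counted from 1. The sequence lengths came from the file headers. The main comparisons used the arms X, 2L, 2R, 3L, 3R and 4, which span 120.4 Mb. The 8 sequences outside these arms (heterochromatic, unplaced and extra scaffolds) were counted separately. Clusters were called shared where they overlapped by at least 1 base. The overlap was tested by moving all clusters of an arm by 1 random offset with wrap-around, in 100000 shifts, with a two-sided permutation p. The smallest p that 100000 shifts can give is 1e-05. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only and treat clusters as independent. Scores of overlapping clusters were paired by the best overlap and correlated with Spearman's rho and Pearson's r, each with a two-sided permutation p from 100000 permutations of the pairs. The number of clusters per arm was tested against the arm's share of the assembled length with a two-sided exact binomial test, adjusted over the 6 arms by the Benjamini-Hochberg method. An arm was called where the adjusted p was under 0.05 in both replicates. Neighbouring clusters are not independent, so these p-values are too small. A permutation of bins of 1 Mb among the arms was therefore added after the data were examined.

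Regions were named by a rule fixed before the data were examined: the 20 clusters found in both replicates with the highest score in the combined list, on the arms. The gene table at hand belongs to release 6 of the genome. Its coordinates were not set beside those of release 5, so regions are given by position and no gene is named. For the same reason 3 planned results were not run: the position of clusters relative to genes, lists of genes with a cluster at the transcription start site, and the base composition of clusters. No reference sequence was used here.

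The alternatives were an overlap of at least 50% of the smaller cluster, clusters with scores above the median of their list, clusters closer than 500 bases joined, all sequences included, each replicate left out in turn, the combined list, covered bases in place of clusters, and width in place of score. For the arms, clusters of replicate 1 found in both replicates were added after the data were examined, as were alternatives for the scores on X. The shift test was tested on simulated data with 1000 shifts per pair of lists. Of 100 pairs of independent lists of up to 4719 clusters, 5 gave p under 0.05. All 20 simulated pairs with a planted overlap of 20% and all 20 with a planted overlap of 5% did so. The simulated clusters were placed with equal probability along each arm. These rates therefore do not cover lists as uneven along the arms as the real ones. The computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and numba 0.67.0, and plots were drawn with Matplotlib 3.10.9.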

Results

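JHDM1, also known as KDM2, is a JmjC-domain demethylase of lysine 36 on histone H3 and carries a zinc finger of the CXXC type. Its binding was profiled by ChIP-seq in wild-type Oregon-R embryos of 14 to 16 h, with 2 ChIP replicates and 2 inputs. The data analysed here are the authors' lists of enriched clusters, 1 per ChIP replicate and 1 combined list, on FlyBase release 5. The lists give a position and a score for each cluster and no read counts, so the depth of each sample is unknown. The labels name no second condition. The comparisons that the design implies are those between the replicates, between the replicates and the combined list, and between chromosome arms.

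JHDM1 clusters covered about the same length of the genome in both replicates. ChIP replicate 1 held 4768 clusters over 9.95 Mb and ChIP replicate 2 held 4805 clusters over 10.0 Mb. The mean was 4786.5 ± 26.2 clusters and 9.97 ± 0.0359 Mb (SD, n = 2). On the 6 arms, the clusters took up 8.13% of the sequence in replicate 1 and 8.18% in replicate 2. Clusters had a median width of 1969.5 bases in replicate 1 and 1940 bases in replicate 2, and none was narrower than 1301 bases in either list. The median score was 0.600 in replicate 1 and 0.629 in replicate 2. The combined list held 11598 clusters over 23.7 Mb, with a median width of 1734.5 bases. Its 11412 clusters on the arms covered 23.4 Mb, or 19.4% of the arms.

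Combined scores on the 6 arms reached 3.48, but the cluster with that score was not found in both replicates. Among the clusters on the arms found in both replicates, those with the highest combined scores lay on X and the large autosomal arms. The highest combined score among these was 2.44, at X:5417551-5419897, where the replicates scored 2.74 and 1.97 (mean 2.36 ± 0.547, SD, n = 2). The next was at 2L:13877066-13880267, with a combined score of 2.28 and replicate scores of 2.30 and 2.51. The clusters at 2R:15612135-15617808 and 2R:9316239-9321192 followed with combined scores of 2.22 and 2.09. On 3R, the clusters at 3R:4492884-4496432 and 3R:13440588-13447042 had combined scores of 2.09 and 2.05. The highest cluster of 3L was 3L:13425041-13429244, with 2.03. The 20 highest clusters found in both replicates had combined scores from 1.85 to 2.44. Their widths ran from 2285 to 6455 bases, with a median of 3136.5. Of these, 7 lay on 2R, 7 on 3R, 3 on 2L, 2 on X, 1 on 3L and 0 on chromosome 4. In 18 of the 20 the score was higher in replicate 1.

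On the arms, the widest clusters found in both replicates were other regions than these. The widest on the arms was 3R:12064888-12085487, of 20600 bases in the combined list, with 16309 bases in replicate 1 and 11057 bases in replicate 2. At X:2186088-2202658 the combined cluster spanned 16571 bases, while the overlapping clusters of the replicates spanned 3955 and 2274 bases. At 3L:17952495-17967051 all lists gave a wide cluster, of 14557 bases in the combined list, 13998 bases in replicate 1 and 13948 bases in replicate 2. These regions were chosen by width after their values were seen.

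Most clusters of one replicate were found in the other. On the arms, 3286 of 4719 clusters of replicate 1 overlapped a cluster of replicate 2, or 69.6% (95% interval 68.3 to 70.9%). In the other direction, 3295 of 4761 clusters were shared, or 69.2% (67.9 to 70.5%). Shifted clusters overlapped in 15.8% ± 0.651 (SD over shifts) for replicate 1 and at most in 29.9%. The Jaccard index of covered bases was 0.488, against 0.0436 after shifting. All of these had a permutation p of 1e-05, the smallest that 100000 shifts can give.

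Wide clusters and clusters with high scores were shared most often. The lists were divided into 10 classes of equal size by score and 5 by width. In the highest class by score, 99.6% of the clusters of replicate 1 and 98.1% of those of replicate 2 were shared. In the lowest class the share was 55.9% in replicate 1 and 75.1% in replicate 2. The share in replicate 2 did not follow the score throughout, since it was 55.7% in the fourth class from the bottom. In the narrowest class by width, 37.1% of clusters in replicate 1 and 36.4% in replicate 2 were shared, against 94.6% and 93.6% in the widest class. Width alone raised the overlap of shifted clusters only from 13.5% to 19.5% between these classes in replicate 1. Shared clusters had a median width of 2077 bases in replicate 1 and 2059 bases in replicate 2, against 1576 and 1549.5 bases for the others. Their median score was 0.640 against 0.543 in replicate 1 and 0.651 against 0.595 in replicate 2.

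**Figure D1:**
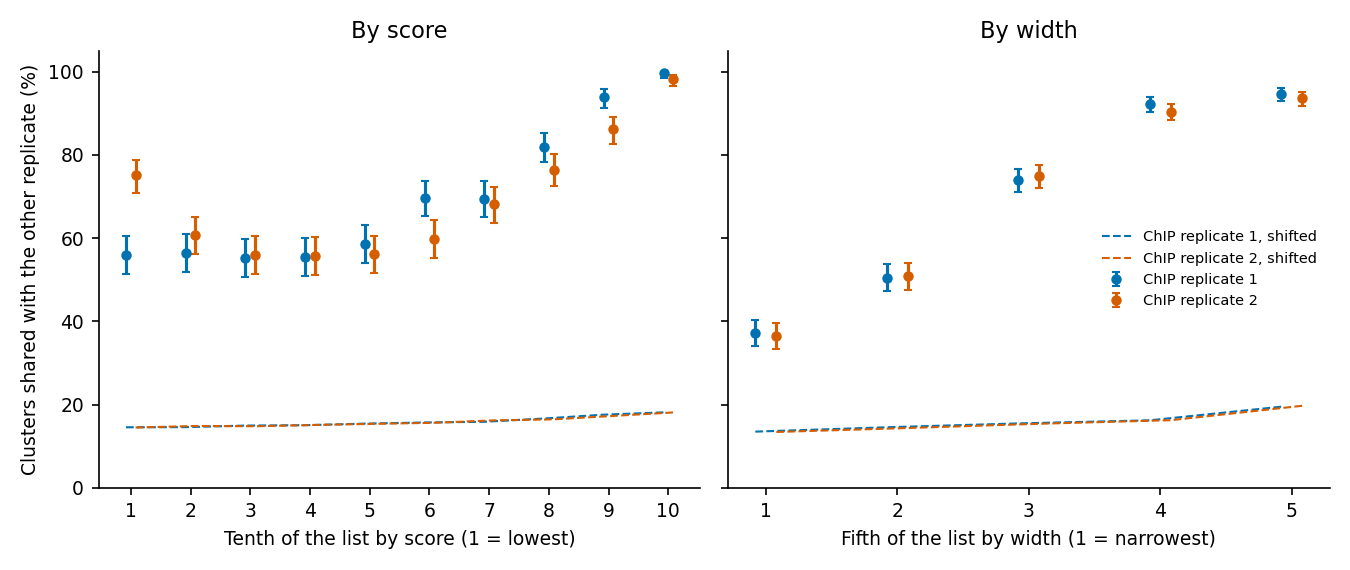
Share of clusters on the arms that overlap a cluster of the other replicate (y axis, %), by 10 classes of score (left) and 5 classes of width (right). Points are the observed shares with exact 95% intervals and dashed lines the mean of shifted clusters, and the shares reach 99.6% in the highest score class of replicate 1 and 94.6% in its widest class.

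Where clusters were shared, their scores rose together. Across 3286 overlapping pairs, Spearman's rho was 0.67 and Pearson's r was 0.81, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. These are correlations across clusters, which are not independent replicates. Within arms, rho was 0.58 on X, 0.69 on 2L, 0.62 on 2R, 0.67 on 3L and 0.68 on 3R. Chromosome 4 had 8 pairs, too few for a comparison with the other arms. The widths of paired clusters followed each other less closely, with a rho of 0.52 and an r of 0.60. The difference between these correlations was not tested.

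**Figure D2:**
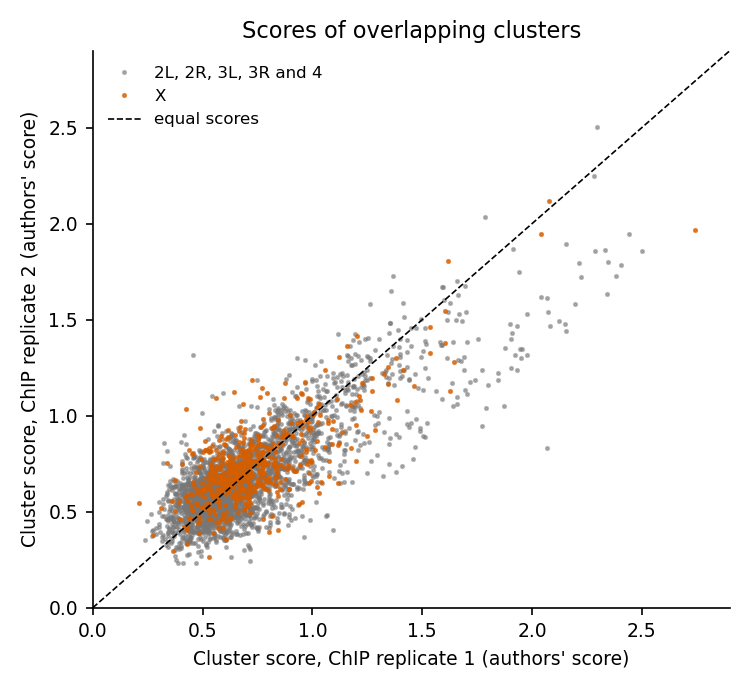
Authors' scores of the 3286 overlapping cluster pairs in ChIP replicate 1 (x axis) and ChIP replicate 2 (y axis), with 1 point per pair, X in orange and the other arms in grey. The dashed line marks equal scores, and the highest point on the x axis is the X cluster with scores of 2.74 and 1.97.

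The combined list held many clusters that neither replicate list held. Of its 11412 clusters on the arms, 3174 overlapped clusters of both replicates, or 27.8% (95% interval 27.0 to 28.6%). A further 1306 (11.4%) overlapped a cluster of replicate 1 only and 1324 (11.6%) of replicate 2 only. The other 5608, or 49.1% (48.2 to 50.1%), overlapped a cluster of neither. Clusters found in both replicates had a median combined score of 0.556 and a median width of 2689.5 bases. Clusters found in neither had 0.417 and 1267 bases, and 54.5% of them were narrower than 1301 bases, the narrowest cluster of either replicate list. Clusters found in 1 replicate only had slightly lower median scores than these, 0.399 for replicate 1 and 0.407 for replicate 2. They were wider, with medians of 1898.5 and 1885 bases. Nearly all replicate clusters were in the combined list, with 31 of replicate 1 and 63 of replicate 2 left outside. The combined list was made from the same samples, so no test applies.

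Clusters were densest on 2R and scarcest on chromosome 4. Arm 2R had 48.3 ± 0.736 clusters per Mb (SD, n = 2), 1.23 times the density over all arms, with adjusted p-values of 7.2e-11 and 9.7e-13 in the exact binomial test. Chromosome 4, the short arm that is largely heterochromatic, had 13 and 9 clusters, or 8.14 ± 2.09 per Mb. This was 0.207 times the density over all arms, with adjusted p-values of 2.4e-10 and 7.1e-13 in the exact test. In both directions the differences between arms were larger than the spread between replicates. In a permutation of 1 Mb bins, chosen after seeing the data, 2R kept its call with adjusted p-values of 0.00558 and 0.00396. Chromosome 4 kept its call with 0.0160 and 0.0111, but it has 2 bins, where 2R has 21, and the second is shorter than 1 Mb. All densities are per assembled length, and how well reads align on each arm was not tested.

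The other arms differed less. Arm 3R had 42.0 ± 0.380 clusters per Mb, 1.07 times the density over all arms, with adjusted p-values of 0.0181 and 0.0136 in the exact test. Arm 2L had 34.5 ± 0.184 and a ratio of 0.877, with adjusted p-values of 2.0e-04 and 2.1e-05 in the exact test. The X chromosome had 36.4 ± 0.189 and a ratio of 0.925, with 0.0181 and 0.0151. Arm 3L had 37.6 ± 0.259 and a ratio of 0.955, which passed in neither replicate (0.112 and 0.118). In the permutation of bins the calls for X, 2L and 3R were lost, with adjusted p-values up to 0.300, 0.261 and 0.296. Among clusters with scores above the median of their list, the ratio for X turned to 1.29 and that for 3R to 0.987.

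**Figure D3:**
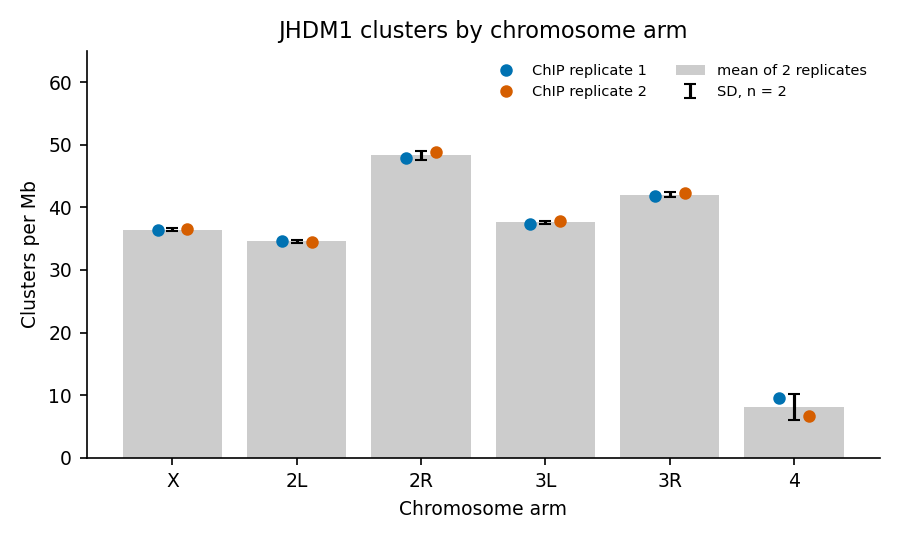
Clusters per Mb (y axis) on each chromosome arm (x axis). Bars are means of the 2 ChIP replicates with SD (n = 2), points are the replicates, and the means run from 8.14 on chromosome 4 to 48.3 on 2R.

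Along the arms the replicates rose and fell together. Over the 118 full bins of 1 Mb, the cluster counts of the replicates had a Pearson's r of 0.927 and a Spearman's rho of 0.894, each with a permutation p of 1e-05, the smallest possible. This is a correlation across bins of the same pair of samples. Bins held 39.6 ± 13.3 clusters in replicate 1 and 40.0 ± 14.0 in replicate 2 (SD over bins). The variance was 4.49 and 4.93 times the mean, so clusters were more uneven along the arms than independent placement gives. The densest bin was 2R:20000001-21000000, with 72 and 87 clusters.

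**Figure D4:**
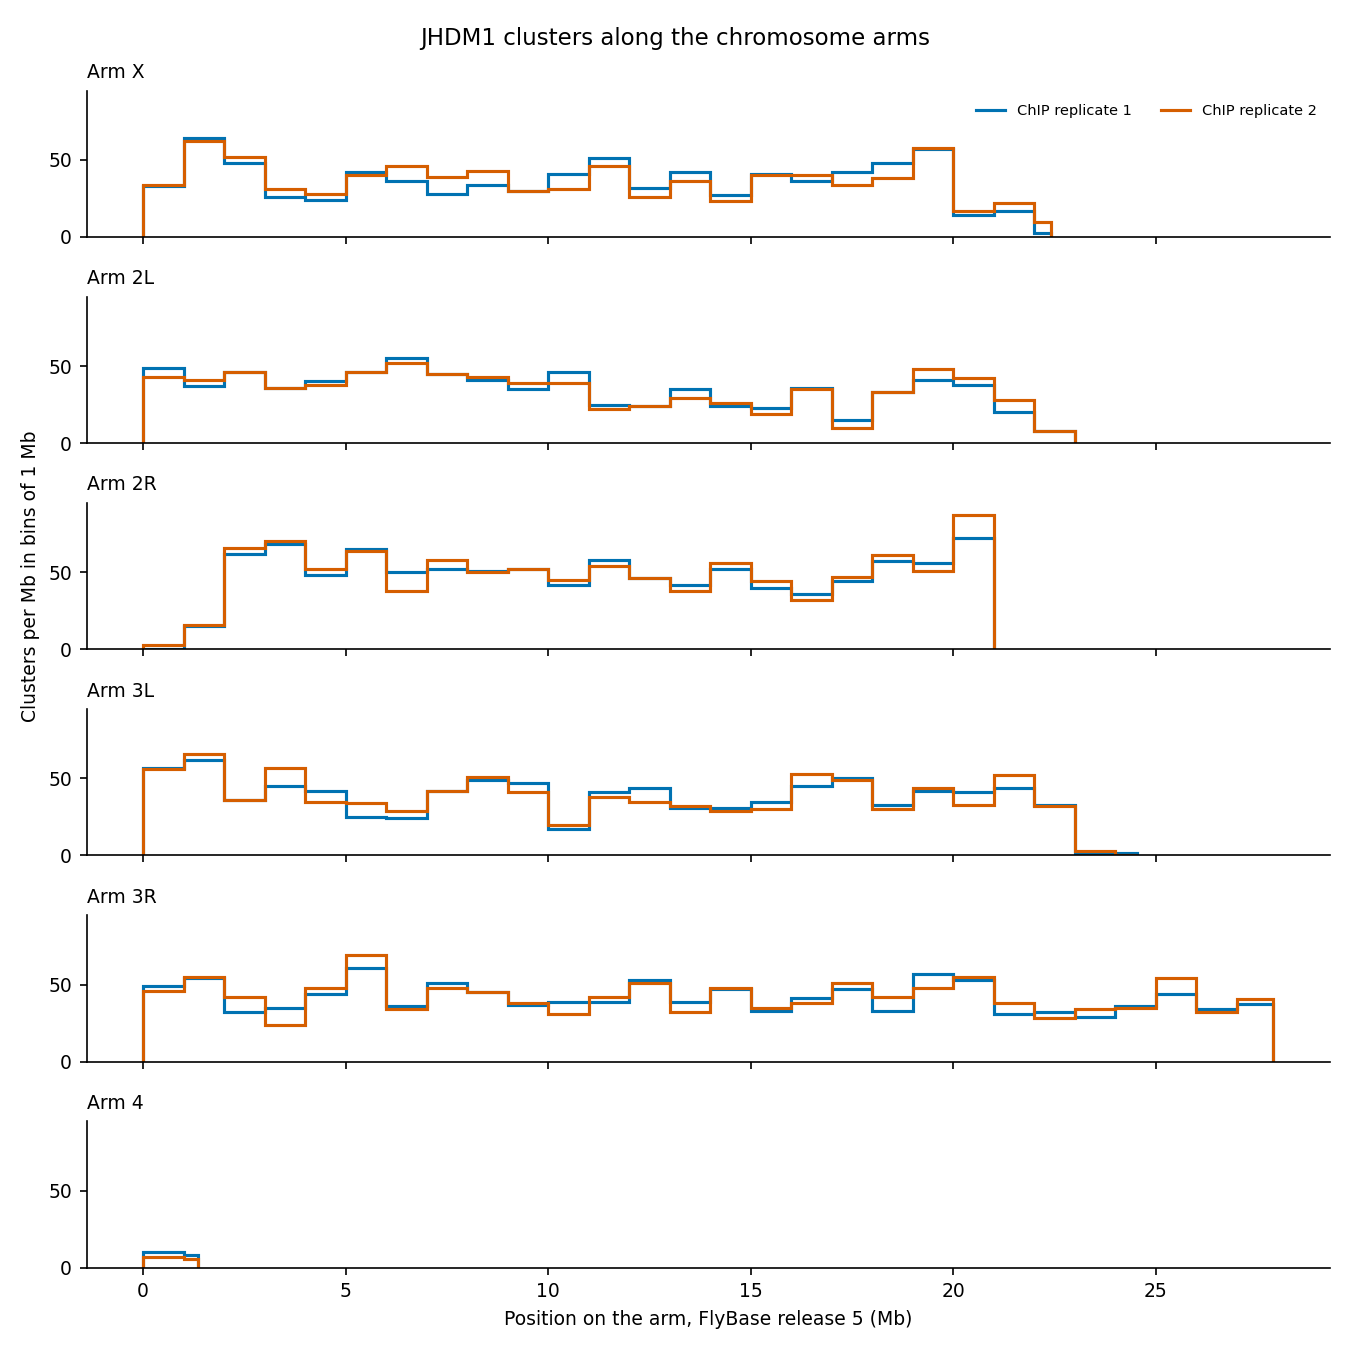
Clusters per Mb (y axis) in bins of 1 Mb along each arm (x axis, position in Mb on FlyBase release 5), for ChIP replicate 1 in blue and ChIP replicate 2 in orange. The highest bin is the one at 20 to 21 Mb on 2R, with 72 and 87 clusters, and bins shorter than 250 kb are left out.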

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

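Clusters also lay on sequences outside the 6 arms, which the comparisons above leave out. There were 49 in replicate 1, 44 in replicate 2 and 186 in the combined list. They are given because they lie in data outside those comparisons, and with no input list here, no background count can be set beside them. Most replicate clusters among these were on U, the set of scaffolds with no place on a chromosome, with 38 in replicate 1 and 33 in replicate 2. U also held 109 clusters of the combined list, of which 28 overlapped clusters of both replicates. The median score on U was 1.71 in replicate 1, 1.80 in replicate 2 and 1.37 in the combined list, against 0.599, 0.628 and 0.434 on the arms. The widest cluster of each list lay there, at U:1987276-2015441, with 28166 bases in the combined list and replicate scores of 2.12 and 2.15. Another, at U:3467800-3487955, had 20156 bases and replicate scores of 2.01 and 1.82. The extra scaffolds, 29.0 Mb in length, held 0 clusters in every list. No explanation was tested for these scores.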

How the results depend on the processing

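Over 16 results, 81 alternative values were computed. Of these, 58 kept their call or stayed within the spread or, for counts of clusters, within 1.5 times the reported count, 15 moved, 4 lost and 2 gained a call, and 2 reversed. Not all of the 58 could have changed. An arm called in both replicates keeps its call when 1 is left out, as does the score difference on X. For covered bases, the distance of either replicate from their mean is always below the SD. Overlap and score correlations between replicates kept their direction and side of the threshold under each alternative run, and the rule for shared clusters does not enter the Jaccard index. With scores above the median of each list there were 2393.5 clusters over 5.77 Mb per replicate, 25.3% of combined clusters were found in both replicates and 51.3% in neither. By construction this setting keeps fewer clusters. Joining clusters gave 4548.5 clusters per replicate, beyond the SD of 26.2 between replicates, over 10.03 Mb, and shares of 31.3% and 46.6%. Leaving out 1 replicate, 39.3 to 39.4% of combined clusters were found in the remaining one and 60.6 to 60.7% were not.

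On the arms, scores above the median reversed X to 1.29 and 3R to 0.987 and gave 3L a call at 0.832. Scores on X are higher than on the autosomes, with medians of 0.666 against 0.586 in replicate 1, so a minimum on the score keeps more X clusters. Clusters found in both replicates, also added after seeing the data, kept the call or its absence on each arm, with ratios of 0.9002 for X and 1.27 for 2R. The combined list gave X 0.971, without a call, and 3L 0.958, with one. With covered bases the ratios were 0.903 (X), 1.25 (2R), 0.952 (3L) and 1.071 (3R). Permuted 1 Mb bins, likewise added, lost the calls for X, 2L and 3R. Bins are fewer than clusters and the measure differs, but the cause of this loss was not tested. The bin values were 0.899, 0.865 and 1.105. Each is the mean bin of the arm over the mean bin of the other arms. They are therefore not comparable with the ratios to all arms. The cause of the other changes was not tested.

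No paired analysis was possible because the inputs have no list here. All alternatives for gene position, gene lists and base composition were not run. Read depth is unknown, so its limit on weak clusters cannot be given.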

Other observations

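All tests in this part were chosen after the patterns were seen.

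Few clusters lay at the centromere side of the assembled sequence on most arms. The end megabases on that side of the 5 large assembled arms held 65 clusters in replicate 1, against 200.0 ± 27.1 (SD) in windows at random places (permutation p = 1e-05, the smallest possible). In replicate 2 they held 72, against 201.8 (permutation p = 2e-05), and the mean ratio was 0.341. The assembled arm 3R did not share this, with 49 and 46 clusters in its window, where 2R had 0 and 3, 3L 1 and 0, 2L 8 and 8, and X 7 and 15. The windows leave out the separate heterochromatic sequences. Of these, 3RHet, of 2.52 Mb, held 6 and 4 clusters. The longest stretch without a cluster in either replicate was 3L:23446422-24410008, of 963.6 kb, although the combined list had 10 clusters in it. At the start of the assembled 3R sequence, on its centromere side, both replicates had a cluster at 3R:4-2245. How well reads align next to the centromere was not tested.

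Cluster scores were higher on X than on the large autosomal arms. The medians were higher by 0.0793 in replicate 1 and 0.0883 in replicate 2, a mean of 0.0838 ± 0.00642 (SD, n = 2). The test used the mean of the median scores of 1 Mb bins. This was higher on X by 0.0828 in replicate 1 and 0.0817 in replicate 2 (permutation of bins, p = 1e-05 in each, the smallest possible). Width does not account for the higher scores on X, since the mean difference within 5 classes of width was 0.0696. At the 75th percentile the difference was still 0.0545 in replicate 1 and 0.0832 in replicate 2, while the mean difference at the 95th was -0.0833. A rise of all X clusters alike could give this if X had fewer strong sites, so the highest scores cannot decide on such a rise. The difference at the 95th percentile minus that at the 5th was -0.147, with intervals below 0 in both replicates. This was first predicted of fewer reads on X raising the score that a region needs to be called. The contrast cannot decide for that, since a raised threshold removes low scores and would not by itself lower the 95th percentile. The difference at that percentile was -0.107 in replicate 1 (95% interval -0.193 to -0.0465) and -0.0594 in replicate 2 (-0.130 to 0.00698). A second contrast was added after the result of the first. It put the excess at the median above that at the 5th percentile by 0.0245 in the combined list (95% interval 0.0119 to 0.0339). In the replicates this was 0.0167 and 0.0228, with intervals that included 0. A raised threshold would act most on the lowest scores, so fewer reads on X cannot be told apart from a difference in binding.

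Strong shared clusters scored higher in replicate 1, in 76.4% of the 165 pairs in the top 5% by score against 48.8% of all pairs. Among 358 pairs with a mean score of at least 1, the BIC of the score difference was lower by 35.7 with 2 normal components, at 0.017 and 0.491, than with 1 (at most -5.81 in 100 simulated normal sets), and the share of pairs in the upper component rose with the minimum score, from 29.4% to 37.8% at 1.2 and 54.6% at 1.5. One candidate explanation was a wider score range in replicate 1 by 1 factor. A first test on the distance from the main axis of these pairs favoured it, with a BIC difference of -11.5. At a minimum of 1.5 this test gave -0.0503 (simulated highest -2.01). A second test, on the axis of all pairs, was added after the first result. It gave 4.88 (simulated highest -8.07), and 6.49 at a minimum of 1.5 (simulated highest -3.70). The answer depends on the axis and the minimum score, so the factor cannot be told apart from 2 sets. Counting noise by itself would leave neighbouring clusters uncorrelated. Strong clusters under 20 kb apart had a Pearson's r of 0.55 for their distances from the axis of all pairs (rho 0.55, 34 neighbour pairs, permutation adjusted p = 0.00248). This r was the highest of the settings tried, and at a minimum score of 0.7 it was 0.22. The score level of neighbours was not adjusted for. The test therefore cannot separate counting noise around a difference that rises with the score from a regional difference. Of the 12 settings of minimum score and distance tried, 8 had a permutation adjusted p under 0.05 for r and 2 for rho with these distances. With the plain difference 8 and 7 did, and none did under 5 kb. No biological explanation was tested, since the labels name no difference in condition between the replicates. Their lists used different input libraries, and whether the inputs gave the difference was not tested.

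Many clusters carry exactly the same score. Taking scores that occur at least 5 times, 69.0% in replicate 1 and 83.0% in replicate 2 differed from the most frequent one by the log2 of a ratio of whole numbers up to 60, within a relative tolerance of 1e-09. With natural or decimal logs, 0 did. In the combined list the share was 18.5%, short of the majority in every list that the test asked for. Ratios of whole numbers above 60 were not tried, so this low share does not count against log2 ratios of larger numbers. In each list the scores that matched did so with log2 only. The score may be a log2 ratio of read counts, but this was not shown for all scores.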
